A study of Mus musculus with 4 samples.

How the data were processed

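RNA was extracted from whole mouse uterus collected on gestational day 4, from 2 wild-type control samples and 2 samples with the progesterone receptor deleted in gland epithelium (Prss29-Cre, floxed Pgr), per the labels. Libraries were made with a NEBNext Ultra II RNA kit and read as paired ends of 150 bases, and base calls were converted with bcl2fastq 2.17, per the series' design text. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with STAR to the mouse genome GRCm39 and counted with featureCounts. Versions, parameters, the annotation release and the strand setting of these tools are not given in the sources used here. Whether reads with more than 1 match were counted is likewise not given, so values of near-identical paralogs and pseudogenes, and of overlapping or antisense genes, are uncertain.

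The authors deposited a table of raw whole-number counts for 57186 Ensembl genes in 4 columns, 1 per sample, with gene lengths, and no row was without a gene. The authors also deposited a table of TPM for 19991 of these genes, with symbols. On checking, every gene in it had a total count of at least 51 and every gene left out a total of at most 50. Its TPM values equal count divided by gene length, rescaled to sum to the same total over the genes kept, to within 3.6e-11. Columns were matched to samples by the column names that the labels give. Total counts were 35149834 and 33843256 in controls 1 and 2 and 31901278 and 29932153 in knockouts 1 and 2. A floor of 3 counts per library equals 0.0863, 0.0855, 0.0907 and 0.107 CPM in that order. Counting intervals and floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. No pair of libraries was identical or close to sampling noise, the lowest chi-square per degree of freedom being 45.2.

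The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with group as the only term, TMM factors and filterByExpr at its defaults (minimum count 10, minimum total 15), which kept 20950 genes. The biological coefficient of variation was 0.309, with 2 residual and 4.77 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The labels call the samples replicates and do not say whether each came from a separate animal, so p-values measure the spread between these samples, which may be technical in part. Each fold change is knockout over control, with its standard error from the fit and a 95% interval. Where a gene had few counts in 1 group, the ratio of normalised counts with an exact binomial interval is given in place of the fitted fold change. Symbols came from the deposited TPM table for 19934 of the tested genes and from a reference table for 890, and 126 had none.

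The tests, the alternatives, the rule for named genes and 47 gene lists of uterine cell types, hormone targets and pathways were written from textbook knowledge before the data were examined. Of these lists, 46 had at least 5 tested members. Each was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 46 lists. An estimated correlation and fry stand beside it. Of the 15 lists called, 3 higher and 12 lower, 0 were called with an estimated correlation (smallest adjusted p 0.72) and 0 by fry (smallest adjusted p 0.202). Members were also tested with p adjusted over the list alone. The named genes are Pgr and Prss29, up to 10 genes per direction past the threshold with a mean of at least 5 CPM and groups that do not overlap, up to 4 members with the smallest p of each list with a member past the threshold over the list alone, and the 2 most abundant members of each other list. Genes named outside this rule, among them Prss28, Lif, Foxa2, Sox9, Fxyd4, Cxcl15, Aldh1a1, Ihh, Areg, Mki67 and all genes first named in the closing section, were chosen after their values were seen.

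The procedure was tested on simulated counts drawn from the means, dispersions and library sizes of these 4 samples, with 100 genes changed 2-fold and 100 changed 8-fold. The changed genes were drawn only from genes with a mean of at least 5 CPM. In the main test 1 of the 100 changed 2-fold and 98 of the 100 changed 8-fold were recovered, with 7.48% false calls. In 1 further run, 1 list of 20 genes was raised by 1 log2 unit. It was called by camera with adjusted p = 4.91e-16, while with an estimated correlation its adjusted p was 0.558 and by fry 0.192. In that run neither of these called a list that was made to change. Simulated genes were drawn independently, whereas estimated correlations in the real lists were −0.095 for gland epithelium, 0.38 for cell proliferation and 0.96 for smooth muscle. The run therefore does not show how often camera with the preset correlation calls unchanged lists whose genes vary together.

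Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), no low-count filter, a stricter filter (mean of at least 1 CPM and 50 counts in total), robust dispersion, a tested fold above 1.5, the replicate number as a block, leaving out each library in turn, leaving out genes within 10 Mb of Prss29 and Pgr, other distances of 5 and 20 Mb, and the gland list without Prss29. Where a library was left out, its group had 1 sample, which was assumed to vary like the other group. A block of crossed replicate numbers was added after the data were seen. Gene neighbours came from the GRCm38 assembly with GENCODE annotation. That is not the build the authors used, so no coordinates are given. Reads were not analysed here, so Pgr exons inside and outside the floxed part could not be counted apart.

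The test of an immunoglobulin allotype first used Jchain, whose outcome was fixed because Jchain had been picked for its fall, and was replaced by one on 7 plasma cell genes outside the immunoglobulin loci. Of these, 5 were tested by edgeR and the 4 with at least 1 CPM in controls were used. The genes and the rule were set before their values were read, except that of Mzb1.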

Results

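Gene expression was measured by RNA sequencing in whole mouse uterus on gestational day 4, around the time when the uterus becomes receptive to the blastocyst. The 4 libraries fell into 2 groups of 2. Control mice were wild type. Knockout mice carried Cre recombinase at both copies of Prss29, a gene transcribed in uterine glands, together with floxed copies of Pgr, which encodes the progesterone receptor, a design meant to delete Pgr in the gland epithelium. The total count was 35149834 and 33843256 in control replicates 1 and 2, and 31901278 and 29932153 in knockout replicates 1 and 2. The comparison of the groups asks which uterine transcripts differ when the glands lack the progesterone receptor. The groups also differ in the presence of Cre and in the disrupted Prss29 locus, and these differences cannot be separated from that of Pgr. The labels used here give no strain, so a strain difference between the groups cannot be told apart either. Values are in CPM (counts scaled to library size, with TMM normalisation), given as mean ± SD with n = 2 per group, and fold changes are knockout over control.

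Pgr RNA did not differ detectably in whole uterus, whereas Prss29 RNA was not detected in the knockout. Pgr (ENSMUSG00000031870) stood at 140.5 and 138.6 CPM in the control libraries and at 130.1 and 146.2 CPM in the knockout libraries. Its log2 fold change was −0.015 with a standard error of 0.21 and a 95% interval of −0.52 to 0.49. The count covers the whole gene in a tissue where stroma, muscle and luminal epithelium also transcribe Pgr, so it does not check the deletion in glands. Prss29 (ENSMUSG00000034039), which encodes a secreted gland serine protease and is the locus that carries Cre, had 1524 and 190 counts in the controls and 0 and 0 in the knockouts. Against a floor of 3 counts per library it was at least 249.4-fold lower in the knockout, or at least 54.8-fold lower without control replicate 1. The 2 controls themselves differed widely, at 43.86 and 5.41 CPM, and the adjusted p over all genes was 0.386 (edgeR quasi-likelihood test, Benjamini-Hochberg).

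Of 11 tested members of the gland epithelium list, 6 fell in edgeR when p was adjusted over the list alone and 0 rose, while none passed when adjusted over all genes tested. DESeq2, which made more false calls in simulated data, called the same 6 lower over all genes. Its adjusted p ran from 9.1e-09 for Ttr to 0.021 for Prss28, while limma-voom called no gene. The list's median log2 fold change in edgeR was −1.91. With Prss29 placed at its bound of −7.96 it could not move, since Prss29 stayed the lowest member. Prss29, whose locus carries Cre, is itself among the 6. Ttr, which encodes the thyroid hormone and retinol carrier transthyretin, went from 8.61 ± 5.25 to 0.527 ± 0.061 CPM (log2 fold change −4.02, SE 0.59). Spink1, a trypsin inhibitor, went from 42.48 ± 22.14 to 9.55 ± 1.71 CPM (log2 fold change −2.15, SE 0.41). Wfdc3, a whey acidic protein family member, went from 14.56 ± 0.083 to 3.86 ± 0.63 CPM (log2 fold change −1.91, SE 0.32).

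The remaining members of the gland list, named after their values were seen, went in both directions. Prss28 is the neighbouring protease gene to Prss29, and the 2 are similar in sequence, so the counting may have split reads between them. It had 771 and 50 counts in controls 1 and 2 and 3 and 4 counts in the knockouts, a ratio of 102.7 with a 95% counting interval of 49.6 to 256.2. The ratio was 12.4 without control replicate 1 and 193.8 without control replicate 2, so the spread between the controls exceeded the counting error. Lif, the gland cytokine required for implantation, went from 32.59 ± 32.71 to 5.12 ± 0.32 CPM (log2 fold change −2.67, SE 0.75), with 55.7 and 9.46 CPM in controls 1 and 2 against 4.90 and 5.35 CPM in the knockouts. Without control replicate 1 its log2 fold change was −0.88. Prss28 and Lif both passed when adjusted over the list alone. Foxa2, the transcription factor of gland development, was at 14.61 ± 1.54 and 9.50 ± 5.67 CPM and did not pass. Sox9 and Fxyd4 had log2 fold changes of −0.20 and 0.041, whose 95% intervals included 0. The gland chemokine Cxcl15 was at 34.07 ± 6.42 and 54.16 ± 26.14 CPM, and the retinaldehyde dehydrogenase gene Aldh1a1 at 10.92 ± 1.64 and 17.97 ± 3.27 CPM. Neither passed in the list.

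**Figure D1:**
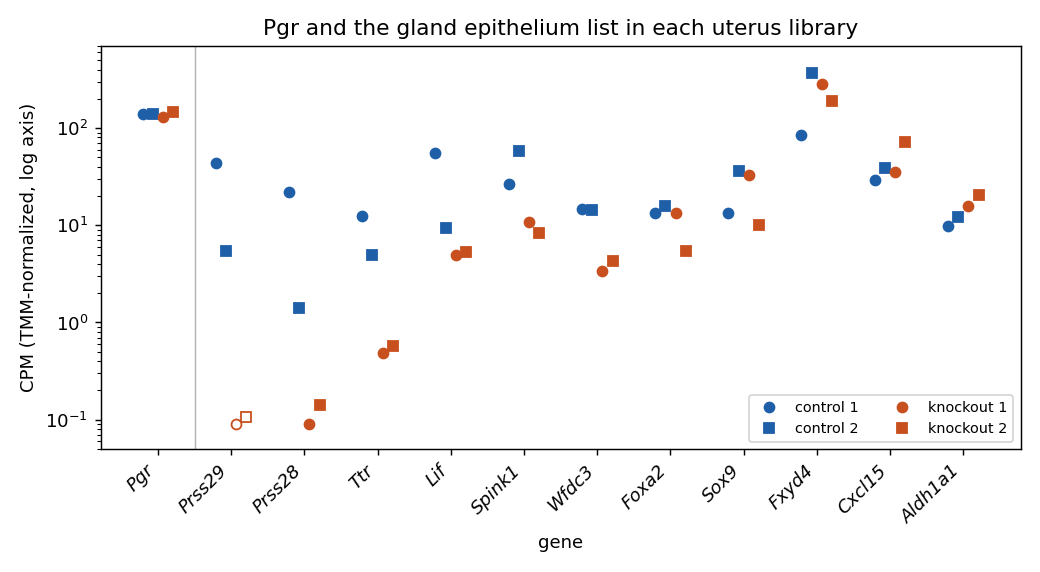
Normalised abundance (CPM, log axis) of Pgr and of the 11 tested gland epithelium genes in each library, with blue for control, orange for knockout, circles for replicate 1 and squares for replicate 2. Open markers are Prss29 libraries with 0 counts, drawn at the floor of 3 counts. Pgr lies between 130.1 and 146.2 CPM in the 4 libraries, while both knockouts lie below both controls for Prss29, Prss28, Ttr, Lif, Spink1, Wfdc3 and Foxa2.

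Tested as a set against all other genes (camera with a preset correlation of 0.01, adjusted over 46 lists), the gland list was lower with adjusted p = 2.43e-05. The adjusted p was 0.72 with an estimated correlation and 0.224 by fry, which asks whether the genes of the list move one way on balance. Without control replicate 1 the median was −0.88, and without genes within 10 Mb of Prss29 and Pgr, which drops both proteases, it was −0.62. It was −1.26 with DESeq2 and −1.27 with no low-count filter, both over the 12 genes of the list, where the main test covered 11. Ttr and Wfdc3 themselves had log2 fold changes of −4.03 and −1.91 with DESeq2, near those of edgeR. In each case the set test, which for DESeq2 used only genes past the low-count filter, still called the list lower.

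Other lists of epithelial genes were not called by camera with all 4 libraries. The luminal epithelium list had a median log2 fold change of 0.11 (adjusted p = 0.56), with Calb1 at 464.8 ± 334.8 and 541.8 ± 84.6 CPM and Msx1 at 308.3 ± 147.2 and 367.0 ± 66.8 CPM. Without control replicate 2 camera called the luminal list higher (median 0.41, adjusted p = 0.0229, and adjusted p = 0.84 with an estimated correlation), while without control replicate 1 its median was −0.16. The pan-epithelial list had a median of −0.10 (adjusted p = 0.54), with the E-cadherin gene Cdh1 at 431.9 ± 22.3 and 337.0 ± 6.03 CPM. For the list of epithelial progesterone targets the median was −0.31 (adjusted p = 0.34) and 0 of 14 members passed over the list alone. Within it, the hedgehog ligand gene Ihh was at 127.5 ± 57.0 and 87.95 ± 21.1 CPM and Areg at 15.13 ± 3.39 and 9.82 ± 5.01 CPM, differences within the spread of the replicates. The endocytic receptor gene Lrp2 was at 746.3 ± 387.8 and 408.6 ± 78.0 CPM, and Sox17 at 414.9 ± 125.8 and 383.9 ± 92.5 CPM. The lists of stromal progesterone and hedgehog targets, of receptivity and LIF signalling and of decidualisation had medians of −0.14, −0.12 and −0.040, with adjusted p of 0.60, 0.70 and 0.75. Il6st, the shared receptor subunit of LIF signalling, was at 713.1 ± 233.5 and 550.9 ± 15.8 CPM, and Hoxa10 at 429.2 ± 44.7 and 493.6 ± 64.4 CPM.

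Among oestrogen-responsive epithelial genes, members moved in opposite directions. Of 16 tested members, 1 rose and 1 fell when adjusted over the list alone, and none passed over all genes. Clca1, which encodes a secreted protein of mucous cells, rose from 0.699 ± 0.785 to 54.1 ± 28.0 CPM, with 5 and 44 counts in controls 1 and 2 and 2445 and 961 in the knockouts. The ratio was 79.4 with a 95% counting interval of 59.9 to 107.5, and it was 44.4 without control replicate 1 and 387.1 without control replicate 2, outside that interval. Lcn2, which encodes an iron-binding secreted protein, fell from 11.25 ± 1.78 to 3.57 ± 0.163 CPM (log2 fold change −1.65, SE 0.33). The list as a whole had a median of −0.067 and adjusted p = 0.85, while its mean was 0.21. Without control replicate 2, 4 members were lower over the list alone. Fgf9 at 3.98 ± 2.48 and 1.18 ± 0.299 CPM and Padi1 with a log2 fold change of 1.40 (SE 0.53) did not pass.

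Cell proliferation genes were lower as a group. All 24 tested members had a log2 fold change below 0, with a median of −0.84, and in 22 of them both knockout libraries lay below both controls. None of the 24 passed alone, over the list or over all genes, although 13 had an unadjusted p under 0.05 in edgeR, and 9 passed over the list alone without control replicate 2 and 13 without knockout replicate 1. Top2a, the topoisomerase of dividing cells, was at 156.0 ± 26.9 CPM in controls and 79.0 ± 11.5 CPM in knockouts (log2 fold change −0.98, SE 0.24). The replication clamp gene Pcna was at 129.7 ± 54.2 and 73.9 ± 22.1 CPM, and the proliferation antigen gene Mki67 at 78.9 ± 14.9 and 39.9 ± 15.1 CPM. The camera adjusted p was 1.29e-15 with the preset correlation, and the adjusted p was 0.88 with an estimated correlation.

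**Figure D2:**
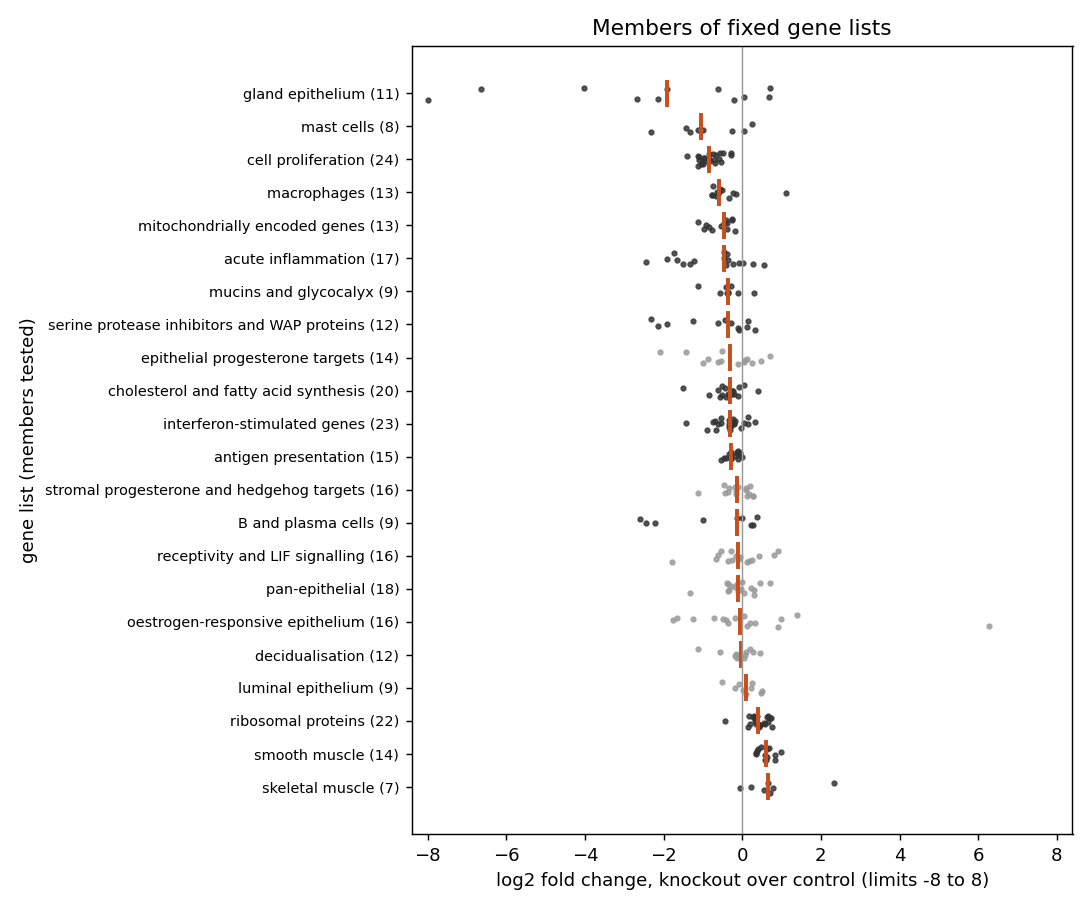
Log2 fold change (knockout over control) of each tested member of 22 gene lists, 1 dot per gene, with the list's median as an orange bar and the number of members in parentheses. Dark dots belong to lists called by camera with the preset correlation, grey dots to lists that were not called, and the fitted value of Prss29, which lies beyond the axis, is drawn at −8. All 24 proliferation genes lie below 0, while the gland list runs from below −4 to above 0 around a median of −1.91.

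Of 9 tested members of the B and plasma cell list, 3 fell in edgeR when adjusted over the list alone and none when adjusted over all genes. DESeq2 called 2 of the 3 lower over all genes, Igkc (adjusted p = 5.5e-14) and Jchain (3.9e-07), while limma-voom called no gene. Igkc, the kappa light chain constant region, fell from 107.9 ± 4.19 to 19.9 ± 0.14 CPM (log2 fold change −2.44, SE 0.21, adjusted p over all genes 0.0613). Jchain, which joins immunoglobulin polymers, fell from 94.5 ± 4.05 to 20.3 ± 7.75 CPM (log2 fold change −2.22, SE 0.31). Fcrla, a B cell Fc receptor-like gene, fell from 0.717 ± 0.167 to 0.117 ± 0.037 CPM, and Mzb1 at 1.29 ± 0.477 and 0.637 ± 0.296 CPM did not pass. The list's median was −0.13 and its mean −0.83, and the median was −0.24 and −0.41 without control replicates 1 and 2 in turn and −0.81 and −0.48 without knockout replicates 1 and 2. With DESeq2, where it also covers members that the low-count filter left out, it was 0.11. The DESeq2 log2 fold changes of Igkc and Jchain were −2.43 and −2.21, near those of edgeR. The list's camera adjusted p was 2.04e-03, and the adjusted p was 0.77 with an estimated correlation. The call was lost with no low-count filter (adjusted p = 0.33, median 0.10) and with a stricter one (0.064).

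Several lists of immune cells and inflammation were also lower by camera. The macrophage list had a median of −0.59, with 12 of 13 members below 0 (adjusted p = 2.43e-05, and adjusted p = 0.72 with an estimated correlation). Its most abundant members were the lysozyme gene Lyz2 at 279.5 ± 111.1 and 179.3 ± 38.2 CPM and the perforin-family gene Mpeg1 at 99.7 ± 32.9 and 66.4 ± 10.4 CPM. The acute inflammation list had a median of −0.46 (adjusted p = 2.43e-05, and adjusted p = 0.72 with an estimated correlation), and it was −0.24 and −0.92 without control replicates 1 and 2 in turn and −0.47 and −1.20 without knockout replicates 1 and 2. Lcn2 was its only member to pass over the list alone, and the chemokine gene Cxcl5 at 2.31 ± 0.247 and 0.814 ± 0.210 CPM, Il6 with a log2 fold change of −1.92 (SE 0.75) and Nfkbiz at 58.2 ± 4.83 and 42.4 ± 0.530 CPM did not. With 1 library left out, 1 member was lower over the list alone without control replicate 2 and 0 in the other runs. Without knockout replicate 1 both set calls were lost, with adjusted p of 0.087 for macrophages and 0.112 for acute inflammation.

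The mast cell list had a median of −1.06 (adjusted p = 4.05e-03, and adjusted p = 0.89 with an estimated correlation), but its most abundant members, Hdc and Gata2, are also transcribed by other uterine cells and had log2 fold changes of −0.26 and 0.043. The list's median was −0.45 and −1.70 without control replicates 1 and 2 in turn and −0.44 and −2.46 without knockout replicates 1 and 2. The mast cell call was lost without control replicate 1 (adjusted p = 0.053), without knockout replicate 1 (0.42) and without genes within 10 Mb of Prss29 and Pgr (0.26). The interferon-stimulated and antigen presentation lists had medians of −0.30 and −0.28 (adjusted p = 6.54e-04 and 0.0283, and adjusted p = 0.89 for both with an estimated correlation). The RNA sensor gene Rigi was at 170.7 ± 8.53 and 116.6 ± 13.1 CPM and Bst2 at 127.1 ± 17.7 and 123.8 ± 24.3 CPM. The class I genes H2-K1 and H2-D1 had log2 fold changes of −0.29 and −0.13. Without control replicate 2 the medians were −0.042 and 0.074, with adjusted p of 0.68 and 0.95. Both calls were also lost without knockout replicate 2 (0.11 and 0.37), and that of antigen presentation without knockout replicate 1 (0.087) and with no low-count filter (0.082).

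Shifts were also called in lists of secreted proteins and lipid synthesis. Serine protease inhibitors and WAP proteins had a median of −0.36 (adjusted p = 8.47e-03), with 2 of 12 members, Wfdc3 and Spink1 of the gland list, lower over the list alone. Slpi had a log2 fold change of −1.26 (SE 0.51), and Serpina3n was at 10.2 ± 13.3 and 2.03 ± 0.653 CPM. Mucins and glycocalyx genes had a median of −0.36 (adjusted p = 0.0351), with Gcnt3 at 70.6 ± 81.3 and 65.6 ± 37.8 CPM and the fucosyltransferase gene Fut2 at 65.5 ± 1.58 and 53.4 ± 1.36 CPM. Cholesterol and fatty acid synthesis genes had a median of −0.31 (adjusted p = 4.18e-03), with the fatty acid synthase gene Fasn at 432.6 ± 77.6 and 353.5 ± 44.4 CPM and Scd2 at 709.6 ± 153.9 and 731.9 ± 131.3 CPM. For each of these 3 lists the adjusted p was 0.89 with an estimated correlation. Without control replicate 1 the adjusted p was 0.055 for the inhibitors, 0.061 for mucins and 0.89 for lipid synthesis, whose median turned to 0.051. Without knockout replicate 1 it was 0.42, 0.16 and 0.42. The mucin call was also lost without control replicate 2 (0.29) and without knockout replicate 2 (0.081), with log2(TPM + 1) values (0.13) and with no low-count filter (0.88).

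Muscle and ribosomal protein genes were higher by camera, with large differences between replicates of one group. The smooth muscle list had a median of 0.60, with all 14 members above 0 (adjusted p = 3.74e-05, and adjusted p = 0.89 with an estimated correlation). Acta2 and Myh11, which encode contractile proteins, were at 1246 ± 1054 and 1199 ± 917 CPM in controls and 1901 ± 714 and 1807 ± 372 CPM in knockouts. The median member was 1.45 higher on the log2 scale in control 1 than in control 2. Without control replicate 2 the list's median was 0.027 (adjusted p = 0.93), and without knockout replicate 2 it was 0.26 (0.063). The skeletal muscle list had a median of 0.66 (adjusted p = 3.72e-03), with Acta1 at 54.8 ± 57.0 and 86.8 ± 48.2 CPM and Tnni2 at 6.10 ± 3.91 and 9.01 ± 1.28 CPM. Its adjusted p was 0.29 without control replicate 2 and 0.054 without knockout replicate 2.

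The ribosomal protein list had a median of 0.40 (adjusted p = 1.30e-04), although its most abundant members, Rplp0 and Rpl4, had log2 fold changes of −0.43 and 0.16. Without knockout replicate 2 its median was 0.060 (adjusted p = 0.74). The mitochondrially encoded genes had a median of −0.47, with all 13 below 0 (adjusted p = 2.39e-04), and mt-Co1 and mt-Cytb had log2 fold changes of −0.18 and −0.39. These genes took 2.66% and 4.52% of the counts in controls 1 and 2 and 2.75% and 2.93% in the knockouts, and without control replicate 2 the median was −0.17 (adjusted p = 0.27). For skeletal muscle, ribosomal proteins and mitochondrially encoded genes the adjusted p was 0.89 with an estimated correlation.

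**Figure D3:**
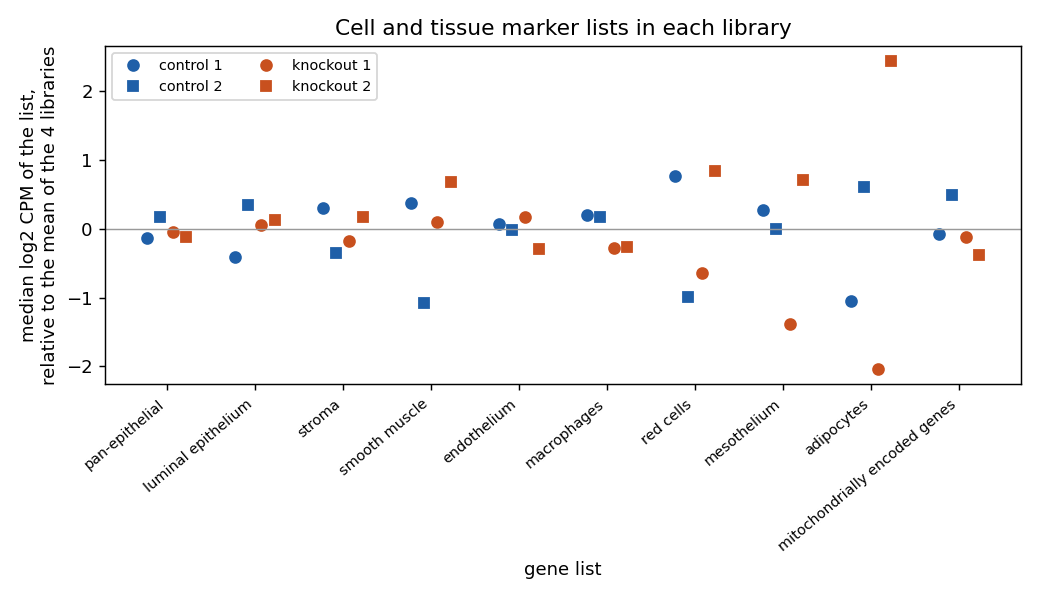
Median log2 CPM of the members of 10 lists in each library, relative to the mean of the 4 libraries, with blue for control, orange for knockout, circles for replicate 1 and squares for replicate 2. Macrophage genes lie at 0.20 and 0.17 in the controls and −0.27 and −0.26 in the knockouts. Smooth muscle genes lie at 0.37 and −1.08 in the controls and 0.10 and 0.68 in the knockouts, and adipocyte genes at −2.04 and 2.44 in the 2 knockouts.

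In the main test camera called none of the remaining lists, and their lowest adjusted p was 0.105, for complement and for T and NK cells. With upper-quartile factors complement stood at 0.083, and with the replicate block adipocytes were at 0.0501 and extracellular matrix remodelling at 0.071. With all 4 libraries complement was called lower with limma-voom (adjusted p = 0.0330), and nerve and glia with the stricter filter (0.0205). Without control replicate 2, complement (0.0165), stroma (0.0165), immediate early genes (0.0114), extracellular matrix remodelling (8.98e-03), the secretory pathway (0.0229) and nerve and glia (0.0460) were called lower. Without control replicate 1, stroma (0.0196) and immediate early genes (0.0139) were called higher and T and NK cells (5.88e-03) lower. Without knockout replicate 2, complement (8.87e-03) and the secretory pathway (5.69e-05) were called lower. With an estimated correlation these adjusted p were 0.69 or more. Among markers of endothelium and stroma, Pecam1 was at 216.5 ± 24.7 and 207.8 ± 40.5 CPM and Col3a1 at 2714 ± 1660 and 2314 ± 624 CPM. The oestrogen receptor gene Esr1 was at 276.6 ± 3.68 and 259.9 ± 23.2 CPM, and the growth factor gene Igf1 at 495.7 ± 33.9 and 489.3 ± 25.9 CPM.

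Gene by gene, over 20950 tested genes, 1 gene changed. Gbp2b (ENSMUSG00000040264), an interferon-inducible GTPase gene with close paralogs that could share its reads, rose from 0 and 1 counts in controls 1 and 2 to 1309 counts over the knockouts, a ratio of 1495 with a 95% counting interval of 267.9 to 59100 (adjusted p = 0.0275, edgeR quasi-likelihood test). The ratio was 751.4 without control replicate 1, and without control replicate 2 it was at least 245.8-fold higher against the floor of 3 counts. Its knockout libraries stood at 23.46 and 19.0 CPM. No gene was lower in the knockout by that test, and the smallest adjusted p among the others was 0.0613. At an unadjusted p under 0.05 there were 630 genes, 256 higher and 374 lower, where 1048 would be expected by chance alone. Both knockouts lay on the same side of both controls in 25.3% of genes, against 33.3% by chance. The same comparison by DESeq2 called 90 genes, 44 higher and 46 lower, and limma-voom called 0. Gbp2b did not pass by limma-voom or with a stricter low-count filter. In simulated data of this size, edgeR recovered 1 of 100 genes changed 2-fold and 98 of 100 changed 8-fold with 7.48% false calls, and DESeq2 recovered 31 and 99 with 22.6% false calls. The simulated changes were placed only in genes of at least 5 CPM, and genes were drawn independently. Larger fitted differences in the real data did not all pass in edgeR, such as Clca1 (76.9-fold higher, adjusted p = 0.2155) and Ttr (16.3-fold lower, 0.237). The simulation therefore does not show that real 8-fold changes would be called. Leaving out 1 library gave 20 genes without control replicate 1, 22 without control replicate 2, 13 without knockout replicate 1 and 12 without knockout replicate 2.

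Genes near the engineered loci were compared with genes elsewhere at an unadjusted p under 0.05, since 1 changed gene in all is too few for a comparison of changed genes. Of 522 tested genes within 10 Mb of Prss29 or Pgr, 1.72% were under it, against 3.10% of genes elsewhere (two-sided Fisher's exact test, p = 0.0717). By the same two-sided Fisher's exact test the shares within 5 Mb and elsewhere were 3.11% and 3.06% (p = 0.864), and for 20 Mb they were 1.89% and 3.11% (p = 0.0574). Neighbours were taken from the GRCm38 assembly, which placed 96.5% of the genes tested.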

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

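The count of changed genes depended on the test and on the libraries, while camera with the preset correlation called the gland and proliferation lists lower in all 14 alternatives under which lists were tested. With an estimated correlation it called neither in any of them (adjusted p 0.60 to 0.99). The count was 1 gene (1 higher, 0 lower) with RLE or upper-quartile factors, robust dispersion, a tested fold above 1.5, and without genes within 10 Mb of Prss29 and Pgr. It was 90 (44 higher, 46 lower) with DESeq2, 0 with limma-voom, 8 (7 higher, 1 lower) with log2(TPM + 1), 7 (6 higher, 1 lower) with log2(TPM + 0.1), 54 (35 higher, 19 lower) with no low-count filter and 0 with a stricter one. Leaving out 1 library gave 12 to 22 genes, 7 to 11 of them higher and 2 to 13 lower, and 9 to 16 lists called in place of 15. The cause of these differences was not tested, although the simulated runs above gave DESeq2 more true and more false calls than edgeR at this size. At this depth and number of libraries, simulated 2-fold changes were mostly missed by edgeR.

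With the replicate number as a block (replicate block), 32 genes were called, 22 higher and 10 lower, 13 lists were called, and the mucin and antigen presentation calls were lost. The labels do not say that the numbers pair samples. Deviations of same-numbered samples from their group means correlated at −0.444 over genes, and those of crossed samples at 0.444. With 2 samples per group these values always mirror each other, so they cannot decide on a pairing. The crossed pairing (control 1 with knockout 2), chosen after seeing the data, called 37 genes, 22 higher and 15 lower.

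The gland list had 4 to 7 members lower over the list alone in the runs tried and 5 without Prss29. Over 112 genes, 1724 of 1782 results under the alternatives kept direction and side of the threshold or stayed uncalled, 2 lost the call (Gbp2b with limma-voom and with the stricter filter), 56 gained one and 0 reversed. A result counted as reversed only where either run called the gene, and Gbp2b alone was called in the main test. Among the 1724, 111 changed sign while uncalled in both runs. Over 46 lists, 593 of 642 results kept their label in the same way, 56 of them with a change of direction but no call in either run. The call was lost in 29 and gained in 15. In 5 results with a call in either run the set test turned direction, and the cause was not tested. The medians in the runs where it turned, with the range over runs that left out 1 library, were 0.051 for cholesterol and fatty acid synthesis without control replicate 1 (−0.64 to 0.051), −0.36 for stroma without control replicate 2 (−0.36 to 0.31; the median with all libraries was −0.12, while the set test pointed upward with adjusted p = 0.94), −0.20 for immediate early genes without control replicate 2 (−0.57 to 0.56) and −3.55 for adipocytes without knockout replicate 2 (−3.55 to 3.01). For mucins with no low-count filter it was −0.30. Over the runs that left out 1 library, other medians ran from −0.49 to −0.042 for interferon-stimulated genes, from −0.46 to 0.074 for antigen presentation, from −0.58 to −0.41 for macrophages, from −0.58 to −0.26 for protease inhibitors, from −0.50 to −0.080 for mucins, from 0.027 to 1.49 for smooth muscle, from 0.084 to 1.44 for skeletal muscle, from 0.060 to 0.67 for ribosomal proteins, from −0.68 to −0.17 for mitochondrially encoded genes and from −1.03 to −0.72 for cell proliferation. The number of changed genes near the engineered loci was 0 at 5, 10 and 20 Mb, which says nothing of those regions when 1 gene changed in all.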

Other observations

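The tests of an interferon response, of a lower share of gland or of all epithelial cells, of the immunoglobulin genes and of neighbours among the genes called by DESeq2 were chosen only after the result was seen. The tests of neighbours among the genes present in 1 genotype, of flanking DNA and of control replicate 1 were set before it.

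Genes outside the fixed lists also differed when DESeq2 was the test, and in all 87 of its 90 genes that edgeR tested the direction was the same. Among abundant genes, the glutathione transferase gene Gsto1 was at 756.5 CPM in controls and 245.6 CPM in knockouts (DESeq2 adjusted p = 9.51e-06), and Gas5, a host gene of small nucleolar RNAs, at 251.8 and 77.5 CPM (1.44e-04). The lysosomal amidase gene Naaa was at 104.6 and 44.3 CPM (0.0408), and the chloride transporter gene Clcn5 at 114.8 and 53.6 CPM (0.0294). In the other direction, Ralgps2 was at 45.3 and 138.4 CPM (9.51e-06) and the sodium-calcium exchanger gene Slc24a3 at 42.0 and 113.0 CPM (1.70e-03). The myeloid integrin genes Itgax, at 24.7 and 5.70 CPM, and Itgam, at 9.04 and 2.62 CPM, were lower, as was the macrophage elastase gene Mmp12, at 7.78 and 1.70 CPM. None of these passed in edgeR, where their adjusted p ranged upward from 0.198. Of the 90 genes, 13 were pseudogenes and all 13 were higher in the knockout, or 14.4% of the calls against 4.42% of the genes tested (two-sided Fisher's exact test, p = 1.11e-04). Gm8730, with the smallest p, was at 10.2 and 588.5 CPM. Pcna-ps2 was at 1.82 and 16.2 CPM, while Pcna went from 129.7 to 73.9 CPM. Whether reads of parent genes were counted at such copies was not tested.

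Markers of tissue that lies around the uterus or enters it varied between libraries of the same genotype. Adipocyte genes were at −2.04 in knockout replicate 1 and 2.44 in knockout replicate 2, as median log2 CPM relative to the mean of the 4 libraries, and mesothelium genes at −1.38 and 0.71. Red cell genes were at 0.77 and −0.99 in controls 1 and 2. With all 4 libraries none of these 3 lists was called between genotypes, with camera adjusted p of 0.68, 0.57 and 0.60, but adipocytes were called higher without knockout replicate 1 (4.32e-04) and lower without knockout replicate 2 (7.33e-04), mesothelium lower without knockout replicate 2 and red cells higher without control replicate 1 (0.0129), each with adjusted p of 0.918 or more with an estimated correlation. The strongest axis of variation over all genes held 53.5% of the variance and separated control 1 and knockout 2 from control 2 and knockout 1, not the genotypes. The next axis held 29.5% and had both controls (56.3 and 5.745) above both knockouts (−33.4 and −28.7). Of the preimplantation embryo list, Eomes was at 7.66 ± 5.45 and 8.34 ± 4.84 CPM and Elf5 at 2.33 ± 1.34 and 2.71 ± 1.51 CPM.

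The lower gland list may reflect either fewer gland cells or altered transcription in the same cells. A loss of gland cells would lower all members alike only if no other uterine cells transcribed them. For 8 of 11 members the 95% interval excluded the list's median, 5 above it and 3 below. Whole-uterus RNA does not show which members other cells transcribe. Of the 3 below, Prss29 carries Cre and Prss28 is its neighbour. The test therefore cannot decide, and a lower share of gland cells stays open. A loss of all epithelium is argued against with all 4 libraries, since the pan-epithelial list had a median of −0.097. Relative to the mean of the 4 libraries, the median log2 CPM of that list was −0.13 and 0.17 in controls 1 and 2. In knockouts 1 and 2 it was −0.045 and −0.11, so the controls themselves differed and the knockouts lay between them. Without control replicate 1, which held most of the Prss29, Prss28 and Lif reads, the median was −0.879, between the values that would have spoken for or against that library as the cause, so the share of the fall that rests on it cannot be told apart from the genotype with 1 control left. Altered transcription in glands without the progesterone receptor, an effect of Cre or of the loss of Prss29 itself, and a strain difference between the mice all stay open. This design cannot separate these hypotheses, and they were not tested for the gland list.

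A group of 7 genes was nearly absent (at most 0.1 CPM) in both libraries of one genotype and present (at least 1 CPM) in both of the other, against 0 and 1 genes in the other pairings of the libraries. They were Gbp2b, Ifi44l, Gm26862, Gm5503 and Gm6334, present in the knockout, and Ifi213 and Prss29, present in the control. Membership of the 7 depends on these cuts. Ifi202b, which they leave out, had 6 counts over the controls and 703 over the knockouts. Its ratio was 133.8, with a 95% counting interval of 61.2 to 365.9. An interferon response is argued against, since the interferon-stimulated list had a median of −0.301, and so is DNA carried along beside the engineered loci, since 0% of the 6 genes other than Prss29 lay within 10 Mb of Prss29 or Pgr (exact 95% interval 0 to 45.9%). A strain difference between the mice may remain. Of the 7 genes, 0 lay within 1 Mb of another, which by the rule set beforehand would have counted against it. A genome-wide difference, however, need not place so few genes side by side. A wider set held 79 genes called by DESeq2 that edgeR tested and that had a known position. Prss28, Prss29 and immunoglobulin genes were left out of it. Of the 79, 18 lay within 1 Mb of another against a median of 8 and a 95th percentile of 16 in 10000 matched draws (permutation p = 0.02). That wider set holds neighbouring relatives such as Itgam with Itgax and Cyp3a59 with Cyp3a25, whose shared regulation or shared reads could give the same clustering. Other neighbours had log2 fold changes of opposite sign, such as Gsto1 (−1.62) with Cfap43 (1.58) and Pla2g4b (−3.51) with Gchfr (2.80). Mfap1b (−1.42) and Slc28a2 (−2.93) moved the same way. Ifi213 (−7.26), 1 of the 7 genes, lay in a run of neighbours with Ifi211 (−1.905), Dusp23 (−1.63) and Atp1a4 (4.76). The labels used here give no strain.

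Igha, the constant region of IgA, was at 341.5 ± 19.8 CPM in controls and 48.6 ± 5.75 CPM in knockouts (log2 fold change −2.81, SE 0.25, edgeR adjusted p = 0.0613, DESeq2 adjusted p = 1.4e-19), lower in both knockouts alongside Igkc and Jchain. Fewer plasma cells of all isotypes would lower Ighg2b and Ighm too. The log2 fold change of Ighg2b was 2.98 (95% interval 2.00 to 3.97), but an allotype could move it. Ighm, which B cells also express, was at −0.0037 (−0.88 to 0.87). The lambda chain genes Iglc1 (−3.09, DESeq2 adjusted p = 0.0147) and Iglv1 (−2.56, 0.0126) fell with the pattern, though neither passed in edgeR. These genes therefore do not decide on that explanation. A different immunoglobulin allotype may remain for Igha and Igkc, and could move Ighg2b: 4 plasma cell genes outside the immunoglobulin loci (Derl3, Mzb1, Eaf2 and Ccr10) had a mean log2 fold change of −0.64 (95% interval over genes −1.60 to 0.314), nearer 0 than the median of −2.44 of the 3 genes, but they are weakly expressed, other cells express them too, and an allotype would not account for Jchain at −2.22. Fewer IgA plasma cells would lower the 3 genes alike; their log2 fold changes spanned 0.592, but the genes were picked because they fell together, so this decides nothing and that explanation stays open. Whether this follows from the genotype, from a difference in housing or strain, or from chance between 2 pairs of samples was not tested.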
